A study of Mus musculus with 14 samples.

How the data were processed

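Liver RNA of 14 samples, 6 with the empty vector (control) and 8 with the Cre vector (knockout), was measured on Affymetrix arrays after WT PLUS labelling. The deposited values are on a log2 scale: the submitters' processing notes name RMA and Partek without versions, and the scale was inferred from the values, which run from 2.13 to 13.8. Per the submitters' processing notes RMA was used, so the values were taken as normalized between arrays and used without further normalization. Intensity arrays give no read depth; the precision of each value is given by the spread between samples, and the background level is not known here.

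The table holds 22206 rows, 1 per transcript cluster. Rows were joined to gene symbols from an NCBI gene table by gene identifier, names only. This gave 19572 rows with exactly 1 symbol, and 2634 rows were not named here. For the 55 genes with over 1 row the row with the highest mean over all arrays was used, leaving 19505 genes, with no filter on level. Some genes that were to be given in any case are not reported here. The descriptions of knockout 7 and 8 repeat the numbers of knockout 5 and 6; no 2 arrays held identical values, so each was counted as a sample, and alternatives averaged these pairs or left out knockout 7 and 8. The labels give the age as 4 months, while the protocol times add up to about 13 weeks.

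The comparison, its tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Knockout was compared with control by lmFit and eBayes in limma 3.58.1 (R 4.3.3), with no trend, no robust option, no covariate and 12 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05 and no fold minimum. The targeted genes were also tested by an exact two-sided permutation of the difference of means over all 3003 splits. Of 48 gene lists, 47 had at least 5 measured members and were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Alternatives were camera with an estimated correlation and fry. For each list, members were also adjusted over the list alone.

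The text names a fixed set of genes in any case, up to 4 members per list with the largest change among those past the threshold, and the 10 largest rises and 10 largest falls past it. Predicted genes, RIKEN clones, small RNA genes and genes whose higher group mean is under 5 on the log2 scale were left out of the last part. Where under 10 genes pass in a direction, those with the smallest p are named up to 10 and said not to pass. Other genes are named only as chosen after their values were seen.

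The array sets were seen in the correlations between arrays. A fit with the set as a term (11 residual degrees of freedom), each set alone, the interaction of knockout and set, exact permutation of list means within the sets (1225 splits, 95% intervals from the fit with the set as a term), and leaving out control 1 and control 4 were therefore chosen after seeing the data. The other alternatives were a filter on dim genes, quantile normalization, median centring, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, the mean of all rows per gene, every row tested alone, an exact rank-sum test, thresholds of 0.01 and 0.1, and a fold minimum of 1.5.

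The fits were tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale, and a list of 30 raised by 0.2. The noise was normal and independent between genes, with each gene's residual SD from the fit with the set as a term. Deviations that genes of an array share were not simulated, and the data follow the set-term fit by design. The shares called may thus be lower on the real arrays. Without the set term 19% and 66% were called, with 1 unchanged gene called. With it 73% and 98% were called, with 15 unchanged genes called.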

Results

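Liver RNA was profiled on Affymetrix gene arrays in 14 samples from male C57BL/6-background mice whose Prkaa1 and Prkaa2 genes are floxed, that is, flanked by sites at which Cre recombinase cuts DNA out. These genes encode the 2 forms of the catalytic alpha subunit of AMP-activated protein kinase (AMPK), an energy-sensing kinase complex completed by a beta and a gamma subunit. After 4 weeks on a high-fat diet the mice received an adeno-associated virus (AAV8) with the hepatocyte-directed TBG promoter. The virus was empty in the control group (6 samples) and carried Cre in the knockout group (8 samples). All mice then had metformin, a glucose-lowering drug, at 50 mg/kg per day for 3 weeks, and livers were collected after a 16 h fast. The series title names the importance of AMPK for metformin's suppression of liver glucose production. The comparison the design implies is knockout against control livers, all exposed to metformin; livers without metformin were not analysed here. The labels describe separate samples without stating that each came from its own mouse, so p-values measure the spread between these samples, which may be partly technical.

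The arrays held 19505 named genes on a log2 scale, with array medians from 5.73 to 5.87. They fell into 2 sets that the labels do not mention. Set 1 held control 1 to 3 and knockout 1 to 4, and set 2 held control 4 to 6 and knockout 5 to 8, so each set had 3 control and 4 knockout samples. Correlations over all rows lay between 0.988 and 0.994 within a set and between 0.951 and 0.963 across sets. Of the 19505 genes, 2112 (10.8%) differed between the set means by over 1 on the log2 scale. Genes of respiratory chain complex I had a median gap, set 2 minus set 1, of -1.34 and ribosomal protein genes of -1.40, against 0.15 for hepatocyte markers. Because both groups were present in each set in the same proportion, the set gap entered the spread within each group and not the difference of the group means. On the second principal component control 1 (23.0) and control 4 (22.1) stood apart from the other 12 arrays (-13.8 to 8.36). Markers of liver endothelium averaged -0.98 in control 1 and -0.69 in control 4 relative to the other controls of the same set, and hepatic stellate cell markers averaged -0.73 and -0.34.

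**Figure D1:**
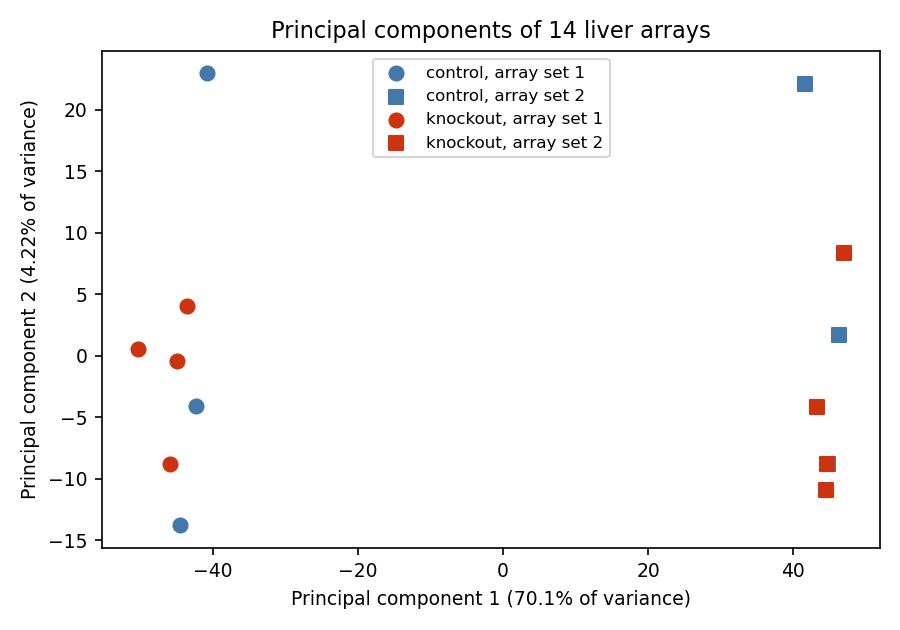
First and second principal component scores of the 14 liver arrays over all genes (unitless scores), with control samples in blue, knockout samples in red, circles for array set 1 and squares for array set 2. The first component holds 70.1% of the variance and separates the array sets, with both groups on each side.

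The targeted genes were lower in the knockout livers. Prkaa2, the alpha2 subunit gene, averaged 8.84 ± 0.10 (SD, n = 3) in control and 7.73 ± 0.11 (SD, n = 4) in knockout samples of set 1, and 9.77 ± 0.12 (SD, n = 3) and 8.63 ± 0.16 (SD, n = 4) in set 2. Prkaa1, the alpha1 subunit gene, averaged 6.54 ± 0.16 (SD, n = 3) in control and 6.05 ± 0.21 (SD, n = 4) in knockout samples of set 1, and 7.35 ± 0.16 (SD, n = 3) and 6.49 ± 0.38 (SD, n = 4) in set 2. For both genes all 8 knockout samples lay below every control sample of their own set. In the planned limma fit, which has no term for the array set, Prkaa2 differed by -1.13 ± 0.25 (SE; adjusted p = 0.519) and Prkaa1 by -0.67 ± 0.21 (SE; adjusted p = 0.987), neither past the threshold of 0.05. Two-sided exact permutation tests over all 3003 splits of the arrays gave p = 0.000999 for Prkaa2 and p = 0.0140 for Prkaa1. With the set as a term, an alternative chosen after seeing the data, the differences were the same and the SE fell to 0.08 for Prkaa2 (adjusted p = 1.92e-06) and 0.13 for Prkaa1 (adjusted p = 0.0302). Prkaa2 was thus at 0.458 and Prkaa1 at 0.629 of the control level. The Prkaa1 call was lost when any of 8 arrays was left out (control 1, 2, 4, 5 or 6, knockout 2, 4 or 5), with adjusted p up to 0.0770. Which exons the array rows cover relative to the deleted part is not known here, and liver cells other than hepatocytes are also in the tissue, so the remaining signal does not measure the share of hepatocytes recombined. None of the other AMPK subunit genes passed the threshold: Prkab1 -0.12 ± 0.08, Prkab2 0.28 ± 0.12, Prkag1 -0.06 ± 0.08, Prkag2 -0.12 ± 0.09 and Prkag3 0.12 ± 0.11 (SE, set as a term). Prkab2 was dim, with means of 3.48 in control and 3.76 in knockout samples, below every array median. As the background level is not known here, its row may not measure the gene. The list of 11 AMPK subunits and upstream kinases had 2 members lower, the 2 targeted genes, which were also the only 2 past 0.05 when adjusted over the list alone.

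**Figure D2:**
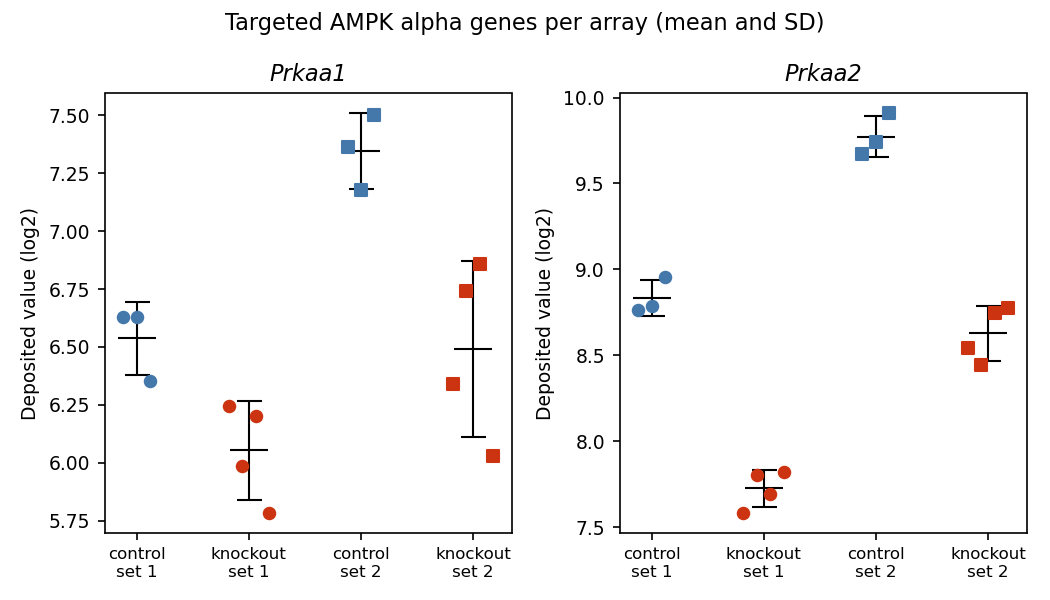
Deposited log2 values of Prkaa1 (left) and Prkaa2 (right) per array, with control in blue, knockout in red, circles for array set 1, squares for array set 2, and black bars for the mean and SD of each group within its set (n = 3 control and 4 knockout samples per set). In each set every knockout sample lies below every control sample, and the means of set 2 lie above those of set 1 for both groups.

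Over all 19505 genes, the planned limma fit called 0 genes at an adjusted p under 0.05, and an exact rank-sum test also called 0. At an unadjusted p under 0.05 the planned fit had 655 genes, against a nominal 975 by chance. The set gap widens the spread within groups in this fit without entering the difference, so chance gives fewer than 975. The 655 genes are therefore no sign that nothing changed, and with the set term 2021 genes had an unadjusted p under 0.05. The 10 genes with the smallest p in each direction, none past the threshold, were on the higher side Tsc22d1, Angptl4, Ephx1 (each adjusted p = 0.181), Tlr12, Cidec, Plin2, Them7, Cdkn1a, Pnpla7 and Pbld2. On the lower side they were Slc3a1, Dsg1c, Prkaa2, Mt1, Arhgap6, Zfp358, Avpr1a, Fndc4, Pter and Lrg1. With the array set as a term, limma called 137 genes, 84 higher and 53 lower in knockout, of which 27 and 13 differed by at least 1.5-fold. Their median SE was 0.173 without the set term and 0.0867 with it. No gene passed for a knockout difference that itself differed between the sets (0 genes for the interaction in limma, 943 at an unadjusted p under 0.05). With 3 control and 4 knockout samples per set this test can miss such differences, so it does not show that the sets agree. In set 1 alone 2 genes passed, Prkaa2 and Adam32, and in set 2 alone 2, Prkaa2 and Xlr3a; Adam32 and Xlr3a were named after their values were seen. The count of 137 depended on single arrays: it lay between 44 without control 4 and 132 without control 3, moved by over 1.5 times for every array except control 3, control 6 and knockout 6, and was 26 without control 1 and control 4 together. Averaging the knockout samples whose descriptions repeat a number (5 with 7, 6 with 8) gave 67 genes, and leaving out knockout 7 and 8 gave 12. Of the 137 calls, 32 held without any 1 array. Single-gene values from here on are knockout minus control on the log2 scale ± SE with the set as a term (n = 6 and 8), and rose or fell is used of genes past the threshold in that limma fit; without the set term none of them passed.

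**Figure D3:**
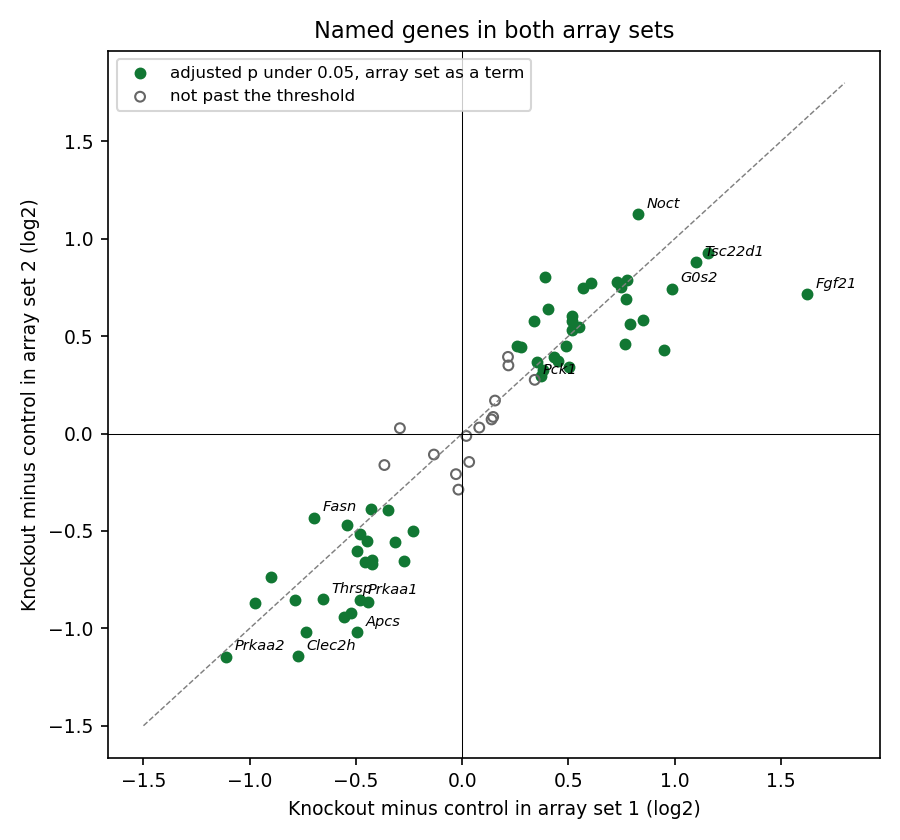
Knockout minus control differences (log2) of the named genes in array set 1 (x axis, 3 control and 4 knockout samples) and array set 2 (y axis, 3 control and 4 knockout samples). Filled green points passed an adjusted p of 0.05 in limma with the array set as a term, open points did not, and the dashed line marks equal values; Prkaa2 lies at -1.11 and -1.15 and Fgf21 at 1.62 and 0.72.

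Genes of fatty acid oxidation and targets of PPAR alpha, the nuclear receptor that drives hepatic fat burning in fasting, were higher in the knockout livers. Of 27 measured members, 26 had a positive difference, 6 rose and none fell, and 18 were higher when adjusted over the list alone. Ehhadh, the peroxisomal bifunctional enzyme, rose by 0.75 ± 0.11, the thioesterases Acot1 and Acot2 by 0.69 ± 0.14 and 0.52 ± 0.11, the peroxisome division gene Pex11a by 0.56 ± 0.08, and Cpt1a, which admits long-chain fatty acids to mitochondria, by 0.36 ± 0.07. The calls of Ehhadh and Pex11a held without any 1 array; those of Acot1, Acot2 and Cpt1a did not, with adjusted p up to 0.0858, 0.104 and 0.0709. The mean over the list differed by 0.25 (95% interval 0.17 to 0.34), by 0.25 in set 1 and 0.26 in set 2. It was the most extreme of all 1225 splits within the sets (two-sided exact permutation p = 0.000816, the smallest they can give; adjusted p = 0.0192 over 47 lists). Camera called the list without the set term (adjusted p = 7.38e-13). With an estimated correlation its adjusted p was 0.00371 without and 0.0632 with the set term. Crat, a carnitine acetyltransferase outside the list, rose by 0.78 ± 0.12.

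The list of lipid droplet and triglyceride turnover genes was called higher by camera (adjusted p = 0.00497; adjusted p = 0.0634 with an estimated correlation). Of 20 members 4 rose and 1 fell, and 5 were higher and 1 lower when adjusted over the list alone. G0s2, an inhibitor of the lipase Pnpla2, rose by 0.86 ± 0.10, the droplet protein Cidec by 0.68 ± 0.09, the monoglyceride lipase Mgll by 0.42 ± 0.09 and Plin2, a droplet coat protein, by 0.41 ± 0.07, while the perilipin Plin4 fell by 0.75 ± 0.16. The list mean differed by 0.11 (95% interval 0.04 to 0.18; exact permutation within sets, adjusted p = 0.0614). Calls of G0s2, Cidec and Plin2 held without any 1 array, and those of Mgll and Plin4 reached adjusted p of 0.119 and 0.0935. In the ketone body list (5 measured, camera adjusted p = 0.576) Bdh1, a 3-hydroxybutyrate dehydrogenase, rose by 0.35 ± 0.07 (adjusted p up to 0.0953 without 1 array), and the list mean was -0.03 (95% interval -0.19 to 0.12) with a median of 0.02. Among 17 lipoprotein genes (camera adjusted p = 0.381; mean 0.03, 95% interval -0.02 to 0.07) Angptl4, an inhibitor of lipoprotein lipase, rose by 0.55 ± 0.08.

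Fatty acid synthesis genes were lower in the knockout livers as a list. Of 19 measured members 16 had a negative difference, 3 fell and 1 rose, and 7 were lower and 2 higher when adjusted over the list alone. Thrsp, a lipogenic regulator, fell by 0.75 ± 0.10, the fatty acid synthase gene Fasn by 0.56 ± 0.09 and Acaca, encoding an acetyl-CoA carboxylase that AMPK phosphorylates, by 0.44 ± 0.08. Elovl5, which elongates polyunsaturated fatty acids, rose by 0.47 ± 0.09. Acacb (-0.15 ± 0.08, adjusted p = 0.545) and Scd1 (-0.26 ± 0.11, adjusted p = 0.402) did not pass. Camera called the list (adjusted p = 0.000161; adjusted p = 0.275 with an estimated correlation), and its mean differed by -0.18 (95% interval -0.31 to -0.06; exact permutation within sets, adjusted p = 0.0639), or by -0.25 (95% interval -0.37 to -0.12; adjusted p = 0.0418) without control 1 and control 4. Control 1 and control 4 had the lowest means of this list among the controls of their sets, so leaving them out enlarges the fall by itself. Calls of Thrsp and Fasn held without any 1 array, while Acaca was lost without control 1 or control 4 (adjusted p up to 0.0558) and Elovl5 without 6 arrays (up to 0.0625). Among 15 glycolysis genes (camera adjusted p = 0.710) Pklr, the liver pyruvate kinase gene, fell by 0.55 ± 0.10 and lost the call without control 2 (adjusted p = 0.0555). The glycolysis list mean was -0.06 (95% interval -0.12 to -0.00).

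Cholesterol synthesis and uptake genes had a median difference of -0.41, the largest of the called lists, and 16 of 18 measured members were negative. Single calls were few: Mvd, mevalonate diphosphate decarboxylase, fell by 0.50 ± 0.11 and Hsd17b7, which also acts in steroid metabolism, rose by 0.60 ± 0.13, whereas 9 members were lower and 1 higher when adjusted over the list alone. Camera called the list (adjusted p = 7.35e-06; adjusted p = 0.187 with an estimated correlation). Its mean differed by -0.33 (95% interval -0.65 to -0.01), which exact permutation within the sets did not call (adjusted p = 0.148). Control 1 and control 4 were low for this list, at -0.78 and -0.47 relative to the other controls of their set. Without both, the mean differed by -0.54 (95% interval -0.79 to -0.29; exact permutation over 225 splits within sets, adjusted p = 0.0418). As control 1 and control 4 were low, leaving them out enlarges the fall by itself. Exact permutation then gave an unadjusted p of 0.00444, the smallest that 225 splits can give. The calls of Mvd and Hsd17b7 did not hold without every single array (adjusted p up to 0.0986 and 0.109).

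Of the genes for glucose output, the process in the study's title, G6pc changed. G6pc, the catalytic subunit gene of glucose-6-phosphatase, which releases free glucose from the liver, rose by 0.73 ± 0.12 (adjusted p = 0.01; 1.66-fold; 0.77 in set 1 and 0.69 in set 2). It was above every control of its own set in 8 of 8 knockout samples, and the call held without any 1 array. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase gene, was 0.31 ± 0.10 (adjusted p = 0.207; 95% interval 0.10 to 0.51), Fbp1, the fructose bisphosphatase gene, 0.00 ± 0.07 (95% interval -0.14 to 0.14) and the coactivator Ppargc1a -0.13 ± 0.13 (95% interval -0.42 to 0.15), none past the threshold. The list of 20 gluconeogenesis and glucose output genes was not called by camera (adjusted p = 0.381), with 12 members positive and a mean of 0.07 (95% interval -0.03 to 0.16). Glycogen metabolism genes (14 measured) had a mean of -0.02 (95% interval -0.10 to 0.06; camera adjusted p = 0.566) and insulin signalling genes (22 measured) of 0.04 (95% interval -0.05 to 0.13; camera adjusted p = 0.948), with no member past the threshold in either.

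Genes of the respiratory chain, at whose complex I metformin is known to act, did not differ measurably between the groups. The mean over 35 complex I genes was -0.00 (95% interval -0.06 to 0.06; camera adjusted p = 0.948) and over 39 genes of complexes II to V -0.02 (95% interval -0.08 to 0.04; camera adjusted p = 0.746), with 0 members past the threshold in limma with or without the set term. These lists had median set gaps of -1.34 and -0.86, so their values rest on the comparison within sets. Mitochondrial biogenesis and dynamics genes (22 measured) had a mean of 0.05 (95% interval 0.01 to 0.09; camera adjusted p = 0.632; exact permutation within sets, adjusted p = 0.0872). Tfam, the mitochondrial transcription factor, was 0.30 ± 0.10 (adjusted p = 0.207) and Mff, a fission factor phosphorylated by AMPK, 0.06 ± 0.07. Autophagy and lysosome genes (33 measured) had a mean of -0.04 (95% interval -0.10 to 0.01; camera adjusted p = 0.458). Of 7 measured metformin transport and drug handling genes (camera adjusted p = 0.576; mean -0.07, 95% interval -0.14 to 0.01) the carnitine transporter gene Slc22a5 rose by 0.35 ± 0.08, a call lost without any of 13 arrays (adjusted p up to 0.112), and Slc47a1 was 0.11 ± 0.06.

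Targets of the stress-responsive transcription factor p53 were higher as a list. Camera called it without the set term (adjusted p = 0.000597; adjusted p = 0.0634 with an estimated correlation) and with it (adjusted p = 0.000198; adjusted p = 0.0420 with an estimated correlation, or 0.0661 without control 1 and control 4). Of 18 members 12 were positive, 1 rose, and 5 were higher and 0 lower when adjusted over the list alone. The riser was Cdkn1a, which encodes the cell cycle inhibitor p21, at 0.75 ± 0.11, a call that held without any 1 array. The list mean differed by 0.20 (95% interval 0.13 to 0.27; exact permutation within sets, adjusted p = 0.0192). Heat shock genes were also higher: 12 of 13 were positive, and Hsp90aa1, a cytosolic chaperone, rose by 0.55 ± 0.09. Camera gave adjusted p = 0.00366 (adjusted p = 0.103 with an estimated correlation), and the list mean differed by 0.19 (95% interval 0.09 to 0.28; exact permutation within sets, adjusted p = 0.0288; adjusted p = 0.104 without control 1 and control 4). NRF2 and glutathione genes had 18 of 21 members positive and 0 called, with camera adjusted p = 4.25e-05 (adjusted p = 0.105 with an estimated correlation) and a mean of 0.17 (95% interval 0.01 to 0.33). Exact permutation within sets did not call this list (adjusted p = 0.148). Without control 1 and control 4 its 95% interval was -0.04 to 0.37, and exact permutation within sets gave adjusted p = 0.270. Fgf21, a fasting hormone of the liver, rose most, by 1.17 ± 0.23 (2.25-fold; 1.62 in set 1 and 0.72 in set 2; adjusted p up to 0.0875 without 1 array). It is in the integrated stress response list, whose 24 members as a group were not called (camera adjusted p = 0.576; mean 0.05, 95% interval -0.01 to 0.11), nor were endoplasmic reticulum chaperones (19 measured; camera adjusted p = 0.352; mean 0.07, 95% interval -0.06 to 0.19). Cell cycle genes (22 measured) had a mean of 0.04 (95% interval -0.13 to 0.22; camera adjusted p = 0.632), which was 0.19 (-0.16 to 0.54) in set 1 and -0.11 (-0.20 to -0.01) in set 2. Whether the sets differ was not tested for this list.

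Acute phase genes, which hepatocytes express in inflammation, were lower as a list, with 21 of 22 negative and 6 lower when adjusted over the list alone. Apcs, encoding serum amyloid P, fell by 0.76 ± 0.14 and lost the call without control 1 or control 2 (adjusted p up to 0.0568). Camera gave adjusted p = 1.14e-05 (adjusted p = 0.103 with an estimated correlation). The list mean was -0.24 (95% interval -0.43 to -0.05), which exact permutation within sets did not call (adjusted p = 0.0872). Without control 1 and control 4 the mean was -0.12 (95% interval -0.27 to 0.04), and exact permutation within sets gave adjusted p = 0.304. Camera with the set term then called the list (adjusted p = 0.00493), but not with an estimated correlation (adjusted p = 0.542). Control 1 and control 4 were high for this list, at 0.43 and 0.31 relative to the other controls of their set. Leaving them out thus shrinks the fall by itself. Of 20 inflammation genes (camera adjusted p = 0.566; mean 0.05, 95% interval -0.07 to 0.17) the chemokine gene Cxcl1 fell by 0.54 ± 0.11 (adjusted p up to 0.0731 without 1 array). Interferon response genes had 21 of 26 members positive and 0 called, with camera adjusted p = 0.000597 (adjusted p = 0.454 with an estimated correlation) and a mean of 0.17 (95% interval -0.06 to 0.39). Control 1 and control 4 were low for this list, at -0.35 and -0.38 relative to the other controls of their set. Without both its mean was 0.04 (95% interval -0.18 to 0.26) and camera with the set term did not call it (adjusted p = 0.395). Immediate early genes had 18 of 22 members negative and 0 called, with camera adjusted p = 0.00471 (adjusted p = 0.199 with an estimated correlation) and a mean of -0.14 (95% interval -0.26 to -0.03). On all 14 arrays, exact permutation within sets (adjusted p = 0.0872) and camera with the set term and an estimated correlation (adjusted p = 0.0632) did not call the list. Without control 1 and control 4, the lowest controls of their sets for this list, the mean was -0.22 (95% interval -0.29 to -0.14). Leaving out low controls enlarges such a fall by itself. Exact permutation within sets (adjusted p = 0.0418) and camera with the set term and an estimated correlation (adjusted p = 0.0467) then called the list.

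Among bile acid genes (20 measured) Cyp8b1, the sterol 12-alpha-hydroxylase gene, rose by 0.46 ± 0.08 and Abcb4, a canalicular phospholipid transporter, by 0.33 ± 0.06, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 0.16 ± 0.08 (adjusted p = 0.526). Camera called this list (adjusted p = 0.0226; adjusted p = 0.132 with an estimated correlation), with a mean of 0.10 (95% interval 0.03 to 0.17). The Cyp8b1 call was lost without control 2 (adjusted p = 0.0623) and the Abcb4 call without 8 single arrays (up to 0.0837). Xenobiotic metabolism genes (23 measured; camera adjusted p = 0.566; mean -0.02, 95% interval -0.15 to 0.10, with a median of 0.06) moved both ways, with 4 higher and 6 lower when adjusted over the list alone. Their 1 call over all genes was the epoxide hydrolase Ephx1, which rose by 0.52 ± 0.08. In the list of hepatokines and growth hormone axis genes (18 measured; camera adjusted p = 0.961; mean 0.06, 95% interval 0.02 to 0.11), Fgf21 and Inhbe, an inhibin subunit gene, rose, the latter by 0.61 ± 0.12 (adjusted p up to 0.0724 without 1 array). Urea cycle and amino acid genes (25 measured) had a mean of 0.01 (95% interval -0.06 to 0.09; camera adjusted p = 0.581) and 0 calls.

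Of the genes outside the lists with the largest changes, Slc35f2 (1.04 ± 0.17), the transcriptional regulator gene Tsc22d1 (0.99 ± 0.15), Noct, which encodes the circadian deadenylase-like protein nocturnin (0.98 ± 0.15), and Omd (0.72 ± 0.14) rose. Clec2h (-0.96 ± 0.15), the desmoglein gene Dsg1c (-0.92 ± 0.16), the vacuolar ATPase subunit gene Atp6v0d2 (-0.88 ± 0.19), E2f8, a cell cycle transcription factor gene (-0.82 ± 0.17), Rcan2 (-0.82 ± 0.16) and the corepressor gene Tle3 (-0.72 ± 0.13) fell. Without 1 array at a time, calls held for Slc35f2, Tsc22d1, Noct, Clec2h and Dsg1c, while adjusted p reached 0.0795 for Omd, 0.117 for Atp6v0d2, 0.104 for E2f8, 0.0829 for Rcan2 and 0.0625 for Tle3. The 10 genes per direction with the smallest p without the set term all passed with it.

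Markers of the cell types of the liver gave no call for hepatocytes or for the immune, endothelial, stellate and bile duct cells. Hepatocyte markers (14 measured) had a mean of -0.02 (95% interval -0.05 to 0.02; camera adjusted p = 0.566). The intervals were wider for other cells: Kupffer cell and macrophage markers 0.09 (-0.25 to 0.43), liver endothelial markers 0.03 (-0.39 to 0.46), stellate cell markers -0.06 (-0.36 to 0.24) and bile duct markers -0.07 (-0.61 to 0.48). Neutrophil markers were at -0.09 (-0.24 to 0.06), lymphocyte and NK cell markers at 0.11 (-0.05 to 0.27; camera adjusted p = 0.0522), dendritic cell markers at 0.10 (-0.12 to 0.32), fibrosis genes at -0.08 (-0.31 to 0.16) and white adipose tissue markers at 0.01 (-0.15 to 0.17). Without control 1 and control 4, camera called the endothelial and stellate lists lower in knockout (adjusted p = 0.000227 and 0.000344; with an estimated correlation adjusted p = 0.522 and 0.465). Pancreatic acinar markers, a sign of neighbouring tissue, were called lower by camera (adjusted p = 0.00497; adjusted p = 0.652 with an estimated correlation), with a mean of -0.25 (95% interval -0.82 to 0.33) that was 0.05 in set 1 and -0.54 in set 2. With the set term (adjusted p = 0.0311) this call was lost when control 6, knockout 3, knockout 6, knockout 7 or knockout 8 was left out (adjusted p up to 0.885). Control 6 stood at 6.41 against 4.80 to 5.39 in the other controls. Only 3 of 12 red blood cell markers were named here, so that list was not tested.

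Genes that vary with the position of a hepatocyte in the lobule, the time of day or sex had list means whose intervals include 0. Members past the threshold within their list went both ways for the female-biased, periportal and clock genes only. When adjusted over the list alone, 3 female-biased genes were higher and 3 lower, 0 and 3 pericentral genes, 1 and 1 periportal genes, and 1 and 1 clock genes. With the set term, fry for changes in either direction called these lists (adjusted p = 0.000716, 1.97e-05, 7.51e-05 and 0.0229), as it did 32 of the 47 lists. Without the set term it called 2 lists. Pericentral genes (14 measured) had a mean of -0.04 (95% interval -0.13 to 0.06; camera adjusted p = 0.381), with the glutamate transporter gene Slc1a2 lower by -0.37 ± 0.08, a call lost without any 1 of the 14 arrays (adjusted p 0.0558 to 0.105). Periportal genes (13 measured) had a mean of -0.00 (-0.10 to 0.10; camera adjusted p = 0.996) and clock genes (19 measured) of -0.03 (-0.11 to 0.06; camera adjusted p = 0.768). Male-biased liver genes (17 measured) had a mean of 0.15 (95% interval -0.04 to 0.33; camera adjusted p = 0.0172; adjusted p = 0.580 with an estimated correlation; with the set term the call was lost without control 2, control 4, control 5 or knockout 1, adjusted p up to 0.0867) and female-biased genes (19 measured) of 0.00 (95% interval -0.14 to 0.15; camera adjusted p = 0.657). Ribosomal protein genes (27 measured) had a mean of -0.05 (95% interval -0.09 to -0.00). They were called by camera with the set term (adjusted p = 0.0309; adjusted p = 0.557 with an estimated correlation) and not without it (adjusted p = 0.581). The call was lost when control 4, control 6, knockout 5 or knockout 7 was left out (adjusted p up to 0.219). In all, camera called 13 of 47 lists without the set term, 8 higher and 5 lower, and 14 with it, all 13 among them. With an estimated correlation 1 list held in each case, fatty acid oxidation without and p53 targets with the set term (lost without control 1 and control 4, adjusted p = 0.0661). Exact permutation of the list means within sets called 4: fatty acid oxidation, p53 targets, heat shock genes and AMPK subunits (mean -0.14, 95% interval -0.23 to -0.06; adjusted p = 0.0256). The AMPK list holds the 2 targeted genes, none of its other 9 members passed, and without control 1 and control 4 its adjusted p was 0.104.

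**Figure D4:**
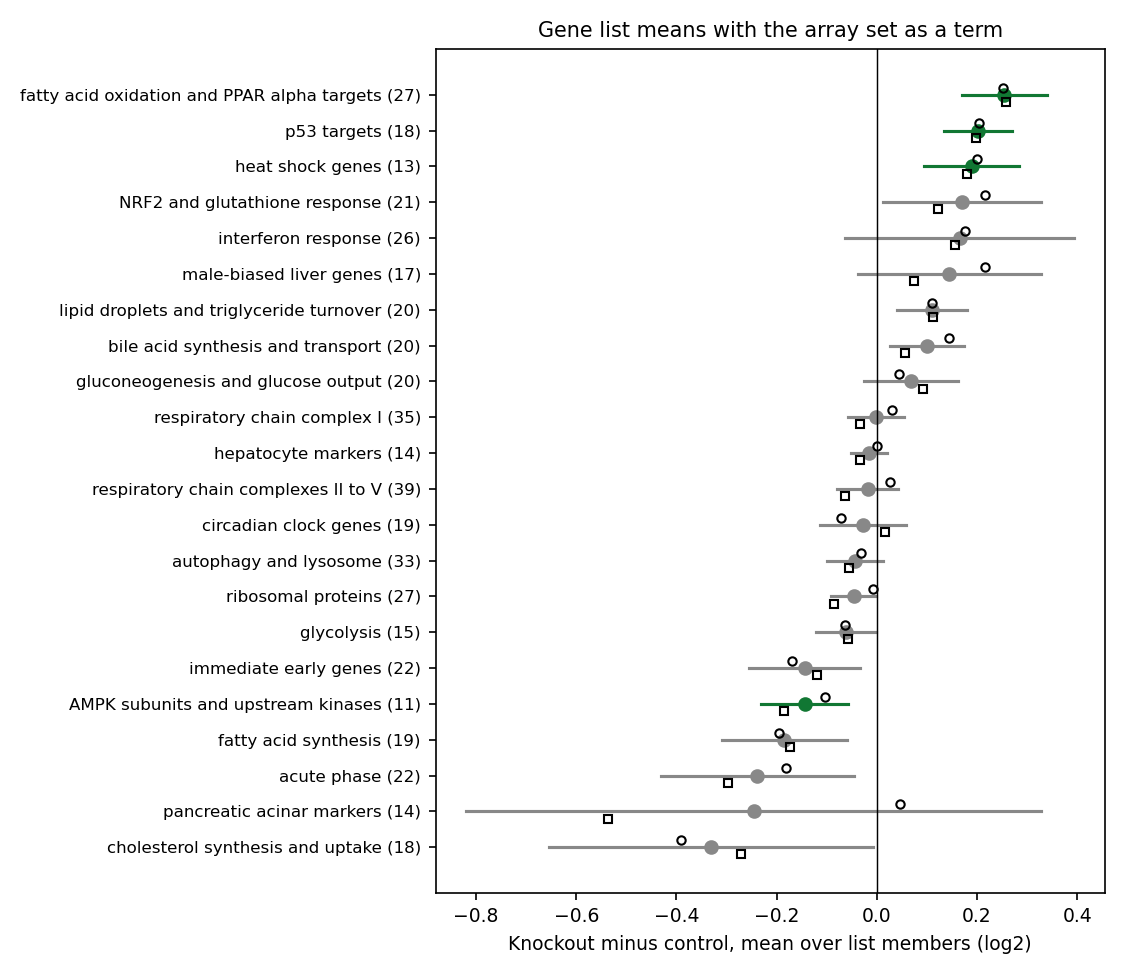
Mean difference over the members of each gene list, knockout minus control on the log2 scale, with the array set as a term (filled points; bars are 95% intervals over the 14 arrays; numbers of measured genes in parentheses), for the lists called by camera or by exact permutation and 7 others. Open circles give the difference within array set 1 and open squares within array set 2; green marks the 4 lists past an adjusted p of 0.05 in exact permutation within the sets, and fatty acid oxidation lies highest at 0.25.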

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

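The 9 values below lay far from those of the other samples of their group by Dixon's test on 236 sets of group values. Chance alone gives about 1 in 20, or 11.8, where the values of a group have a single spread. Each group here pools both array sets, so that rate need not hold, and outliers in items with a wide set gap can be missed. No explanation of the 9 values was tested. Of single genes, Arhgap6 was low in control 1 (6.40, other controls 6.76 to 6.92), Plin2 high in control 5 (11.6, others 11.4 to 11.5) and Prkab2 low in control 2 (2.98, others 3.43 to 3.66). Tlr12 was high in knockout 2 (7.94, other knockouts 7.20 to 7.49). Of list means, bile duct markers were high in control 3 (7.19, others 5.62 to 5.93) and in knockout 1 (7.21, others 5.51 to 6.08), and pancreatic acinar markers in control 6 (6.41, others 4.80 to 5.39). Immediate early genes were low in control 1 (6.53, others 6.78 to 6.93) and male-biased liver genes high in control 6 (11.8, others 11.3 to 11.5).

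Among the 2634 array features without a gene name here, 3 passed an adjusted p of 0.05 in limma with the array set as a term, all 3 higher in knockout, and 0 without it. They were not analysed further.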

How the results depend on the processing

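Tests using the array sets, or leaving out control 1 and control 4, were chosen after the result was seen; where a call ended the cause was not tested. Without the set term the count of changed genes was 0. It was 1 with the replicate block (0 higher, 1 lower: Prkaa2, -1.32, adjusted p = 0.0193), 137 with the set term (84 higher, 53 lower), 2 in set 1 alone (1 higher, 1 lower) and 2 in set 2 alone (0 higher, 2 lower). The block fit compared samples of the same number, so knockouts without a same-numbered control did not count in its difference. Number 4 had its control in set 2 and its knockout in set 1. Without the set term the set gap thus entered the block value of -1.32, unlike the -1.13 of the planned fit. Leaving out single arrays gave 0 to 1 changed and 0 to 1 higher, the 1 being Tsc22d1 without control 6 (1.13). The exact rank-sum test called 0 genes: 35 had its smallest p, 0.000666, where 260 were needed. Prkaa1 was -0.67 with the set term, and Prkaa2 -1.13, -1.11 in set 1 and -1.15 in set 2. Of 13 lists called by camera, 1 passed with an estimated correlation, and fry called 2.

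With the set term, 137 became 270 without dim genes (169 higher, 101 lower; 125 shared), 325 with trend and robust (201, 124; 135 shared), 2 with the replicate block (1, 1: G0s2 and Prkaa2), 67 with arrays of repeated numbers averaged (45, 22; 63 shared), 12 without knockout 7 and 8 (8, 4; 12 shared) and 26 without control 1 and control 4 (14, 12; 19 shared). It was 18 at an adjusted p of 0.01 (15, 3: Prkaa2, Thrsp and Rdh16f2 lower), 242 at 0.1 (146, 96), 40 with the fold minimum (27, 13), 2 in set 1 (1, 1) and 2 in set 2 (0, 2). Single arrays left out gave 44 to 132 changed, 30 to 84 higher and 14 to 48 lower. Quantile normalization, median centring, array weights, mean rows and all rows kept the count within 1.5 times. Prkaa1 was -0.55 with the replicate block (adjusted p = 0.280), -0.62 without knockout 7 and 8 (0.0717), -0.64 without control 1 and control 4 (0.124), -0.48 in set 1 (0.412), -0.85 in set 2 (0.490), -0.67 at the 0.01 threshold, and -0.73 to -0.58 without single arrays. Against 14 lists called by camera, 1 passed with an estimated correlation, 4 by exact permutation (3 among the 14) and 10 by fry (8 among the 14).

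Over 812 alternatives of the other named genes, 523 kept direction and side of the threshold, 283 lost the call and 6 reversed, all in genes never past it: Fbp1 with quantile normalization (-0.0025), the replicate block (-0.017), knockout 7 and 8 left out (-0.024) and set 2 alone (-0.012), Ppargc1a in set 2 alone (0.027) and Prkag1 in set 1 alone (0.033). With single arrays left out, Fbp1 changed sign in 6 of 14 cases and Ppargc1a in 1. Over 209 of the lists 159 kept both, 49 lost the call and 1 reversed: pancreatic acinar markers had a median of 0.0657 in set 1 alone (adjusted p = 0.522). Replicate numbers did not pair the groups: within sets, same-numbered deviations correlated at 0.0229 to 0.0871, and 1 of 6 controls best matched the knockout of its number. Background was not measured here, so it is not known which dim genes it limits.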

Other observations

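The tests of the set gaps over all genes, ribosomal protein genes and hepatocyte markers, the use of Noct and of the lipoprotein and urea cycle lists, and the genes named in this paragraph and the next were chosen after the result was seen. In the cholesterol list, the regulator gene Srebf2 (-0.33) and the pathway genes Idi1 (-0.70), Fdps (-0.67), Nsdhl (-0.55) and Hmgcs1 (-0.50) were lower in knockout when adjusted over the list alone (limma with the set term, n = 6 and 8, adjusted p 0.0122 to 0.0349). Over all genes none of these passed (0.163 to 0.346).

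In the xenobiotic list, which camera did not call (adjusted p = 0.566), Cyp2b9 (-1.14), Cyp2b10 (-0.53) and Cyp2b13 (-0.37) were lower and Cyp3a11 (0.33), Cyp3a25 (0.26) and Cyp3a41a (0.43) higher when adjusted over the list alone (limma with the set term, adjusted p 0.0119 to 0.0141; over all genes 0.127 to 0.198). Of the acute phase genes, Lcn2 (-1.15), Stat3 (-0.37) and Lbp (-0.42) were also lower when adjusted over the list alone (adjusted p 0.00444 to 0.0251; over all genes 0.0608 to 0.191).

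With the set term, 1 of 100 splits within the sets, the real one, gave as many as 137 genes, and the highest other gave 1. A chance split within the sets is thus an unlikely source of 137 genes, to the 1 in 100 that these splits can show. Only part of the 1225 possible splits was drawn, and the set term was chosen after the planned fit called 0 genes. The test takes each array as a separate sample, although the descriptions of some knockout samples repeat a number. Without the set term 100 of 100 splits gave at least the real count of 0, and the highest other gave 3, so that count excludes nothing.

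For the higher fatty acid oxidation and PPAR alpha target genes, 3 technical explanations were tested. Uneven makeup of 1 array set predicted that the list mean is not higher in knockout in 1 of the 2 sets. It was higher in both, and the lower of the 2 lower interval bounds within sets was 0.0645. Sampling at different times of day predicted that the intervals of Arntl, Dbp and Nr1d1 reach 1 from 0, but the widest, of Arntl, reached 0.653. Dbp was -0.01 (95% interval -0.18 to 0.16), and the mean of the 19 clock genes was -0.03 (95% interval -0.11 to 0.06). The predicted size was thus not reached. A time difference that moves these genes by less stays open. Its effect on the fatty acid oxidation genes was not tested, and the circadian gene Noct rose by 0.98. A larger share of hepatocytes predicted hepatocyte markers higher by at least 0.127, but their upper bound was 0.0199. Lipoprotein and urea cycle genes had upper bounds of 0.07 and 0.09, so hepatocyte genes showed no general rise of that size. Controls of set 2 lay 0.22 above those of set 1 for the markers, a gap of unknown cause. It does not show that these bright markers (control mean 12.6) follow the share of hepatocytes, so a larger share is not excluded. The loss of AMPK and an effect of Cre itself were not separated, since no mice with Cre and unfloxed genes were analysed here.

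The rise of Cdkn1a may reflect a p53 response to Cre or to the vector. Both groups received a vector, but whether like amounts reached their livers was not examined here, so the vector is not excluded. A response to Cre predicted a mean rise of over 0.2 in Mdm2, Ccng1, Phlda3 and Eda2r, and their mean was 0.363 (95% interval 0.170 to 0.555; exact permutation within sets, p = 0.00327). All 4 are members of the p53 target list that was higher as a whole, so their mean is not separate support. None of the 4 passed in limma with the set term (adjusted p 0.0504 to 0.568), and Phlda3 was 0.53 in set 1 and -0.03 in set 2. A p53 response to the vector or to the loss of AMPK predicts the same, so the test does not separate these.

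For the split into 2 array sets, 1 shift common to all genes of an array predicted wide gaps on 1 side only, but 729 genes were higher and 1383 lower in set 2 by over 1. Array medians lay between 5.73 and 5.87, so a common shift of over 1 was already absent and this count adds no test of it. A shift of the whole intensity scale predicted more calls without the set term after quantile normalization, but limma then called 0 genes. It moved values by a median of only 0.05, so the intensity scales were already alike. Ribosomal protein, urea cycle and lipoprotein genes averaged 11.9, 11.4 and 11.2 in control 2 of set 1, with median set gaps of -1.40, 0.18 and 0.12. For these genes, at like levels, the opposite directions argue against a shift that depends on intensity alone. Processing that acts on single array features stays open, as the set gap over ribosomal protein genes had an SD of 0.907, between the values that would have decided. No biological explanation of the sets was tested.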
